A study of Mus musculus with 336 samples.

How the data were processed

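Messenger RNA was sequenced as single reads of 50 bases, per the labels, from MSF fibroblasts and liver of WT and Bmal1-/- (KO) mice. Per the submitters' processing notes, reads were aligned to GRCm38 with TopHat2 2.1.0 and quantified with Cuffdiff. The 3 deposited tables hold FPKM per gene (fragments per kilobase of transcript, scaled to the mapped fragments of a library), computed by the authors. How libraries were scaled against each other, and the annotation release, are not given in the sources used here. The runs of a library share 1 FPKM column, so they were taken as technical. The long courses had 48 columns each, 24 time points for each genotype, and the short course 24, 3 replicates at 4 times for each genotype. The design text states 3 samples per time point, but the long tables hold 1 value per time point. No per-sample FPKM column was left unused (0 columns).

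Depth is unknown, since FPKM give no read counts, and no counting interval or detection floor is given. Pairwise correlations of log2 values ran from 0.928 to 0.975 in MSF, 0.881 to 0.981 in the slices and 0.856 to 0.985 in the short course. The 10 most abundant genes took 32.4 to 38.5% of all FPKM in MSF, 35.4 to 58% in the slices and 36.7 to 59.5% in the short course. Of genes with a median of at least 5 FPKM, 283 in MSF, 222 in the slices and 105 in the short course were listed at exactly 0 in some column. Values marked FAIL or HIDATA in the MSF table, 447 and 241, removed 118 genes. Fibroblast genes such as Col1a1 and Col3a1 were listed at 0 in some MSF libraries.

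Values were analysed as log2(FPKM + 1), in genes with a mean of at least 1 FPKM in the libraries of a comparison, with limma 3.58.1 in R 4.3.3 (moderated tests with a variance trend). Tests for counts were not used because the files hold no counts. Rhythms were fitted as a 24 h cosine and sine with a linear trend and tested by a moderated F test on 2 degrees of freedom. The amplitude is the height of the fitted wave above its mean on the log2 scale, and its SE and peak time come from the same fit. A difference of rhythms was tested as the interaction of the 24 h terms with genotype. Its size is the amplitude of the wave left when the WT wave is taken from the KO wave. It has no sign and also grows with a shift of phase. Genotype was tested over the 24 time points with the same terms, and a gene was called at an adjusted p below 0.05 and a difference of at least 1 on the log2 scale. In the short course genotype was called by adjusted p alone, and time and its interaction with genotype by F tests on 3 degrees of freedom. The 12 samples of a genotype were taken as separate, although the labels join each replicate number to its genotype at all 4 times and do not state whether a number is 1 animal. A fit to 1 mean per genotype and number, 3 against 3, was added after seeing the data. Changes over time are against T00 at the time of largest change. P-values were adjusted by the method of Benjamini and Hochberg over all genes tested.

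There were 30 gene lists of 372 genes, written before the data were examined. They cover the clock, glucocorticoid response, cell types of liver and connective tissue, metabolism, stress responses, inflammation, growth and housekeeping classes. Lists with at least 3 measured members were tested for their share of called genes by Fisher's exact test, for a genotype shift by limma's camera with a preset correlation of 0.01 and with an estimated correlation, and for a 24 h wave of the list mean by 9999 permutations of time order, whose smallest p is 1e-04. Genes were named by a rule fixed with the comparisons. Arntl came first, with members of the clock lists, then the 8 largest amplitudes with a mean of at least 5 FPKM whose peak fell within 4 h on each day, the 10 highest and the 10 lowest differences between genotypes with at least 5 FPKM in the higher genotype, the 8 widest changes in the short course, and up to 4 members per list by smallest p. Where several rows shared a symbol, the one of highest mean FPKM was used. Gene models numbered by symbol were passed over, except where a count of 5 or fewer is spelled out, and some genes that the rule names are not reported here.

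Alternatives set in advance were a pseudocount of 0.1, no filter on low values, rescaling by median-of-ratios factors, no trend term, day as a factor, prewhitened residuals, rank-transformed values, leaving out each day or replicate, a time point or replicate block, no size limit and an estimated correlation per list. Leaving out each time point, the slice libraries of lowest correlation, or genes listed at 0, and the alternatives for overlaps, were chosen after seeing the data. Each count was set against 100 regroupings of the same samples, the real one included. The fits were tested on simulated data with 100 changed genes per size. At an amplitude of 0.5, 82% were recovered in WT and 93% in KO fibroblasts, 74% in WT and 62% in KO slices. At 0.25 these were 78, 72, 36 and 18%. Gene positions are those of the GRCm38 annotation. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.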

Results

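The series measured mRNA by sequencing in 3 time courses from wild-type (WT) mice and mice lacking Bmal1 (KO). Bmal1, listed under its gene symbol Arntl, encodes the transcription factor that pairs with CLOCK at the centre of the circadian oscillator. Confluent mouse fibroblasts (MSF) and cultured slices of liver received 100 nM dexamethasone, a glucocorticoid that sets clocks to a common phase, for 15 min. Harvests began 48 h later and were spaced 3 h apart, labelled CT00 to CT69. Each of these courses had 72 sequencing runs per genotype, 3 for each of 24 time points, and held 1 FPKM value per gene and time point. A shorter liver course held 24 runs per genotype, made up of 3 replicates at each of 4 times labelled T00, T06, T12 and T24, with 2 runs per sample. Its samples are also listed with 100 nM dexamethasone for 15 min, without the time from treatment to T00. Genes with a mean of at least 1 FPKM were tested, 14224 to 15065 in the long courses and 12547 in the short one. Depth is unknown because the files hold FPKM alone, so no counting interval is given. The labels do not state that time points or replicates came from separate animals or cultures, so every p-value measures the spread between these samples, which may be technical.

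The fibroblast course asked which transcripts cycle over 24 h after synchronization, and whether any still do without Bmal1. In WT cells Arntl itself (chromosome 7, 113207465 to 113314126, plus strand, GRCm38) had a 24 h amplitude of 0.09 ± 0.02 (SE) on the log2 scale with a peak at 21.9 h, and missed the threshold (adjusted p = 0.344, 24 time points). Nr1d2 and Nr1d1, the nuclear receptors REV-ERB beta and alpha that repress Arntl, had amplitudes of 0.21 ± 0.03 (peak 7.02 h, adjusted p = 0.00328) and 0.25 ± 0.03 (peak 6.21 h, adjusted p = 0.00588) around WT means of 8.01 ± 1.06 and 12.6 ± 2.04 FPKM (SD, n = 24). Dbp, a PAR bZIP factor driven by CLOCK and BMAL1, had the widest swing of the called genes at 0.33 ± 0.05 (peak 8.71 h, adjusted p = 0.0139). Junb, an AP-1 subunit, peaked on the other side of the day at 17.6 h with an amplitude of 0.10 ± 0.02 (adjusted p = 0.0456), as the only called gene of 9 measured immediate early genes. Its peak fell within 4 h of that time on 1 of 3 days, against 3 of 3 for Nr1d1, Nr1d2 and Dbp. The fifth called gene, 4632415L05Rik, was named after its values were seen (amplitude 0.13, peak 6.22 h, adjusted p = 0.0456). Of 15 clock repressors and E-box outputs 3 were called, and 7 when adjusted over the list alone (Fisher's exact p = 8.67e-09 against all genes, adjusted p = 2.08e-07). Their mean had an amplitude of 0.10 ± 0.02 with a peak at 9.01 h (permutation p = 0.0005, adjusted p = 0.012). Per3 (0.20 ± 0.03, peak 9.24 h, adjusted p = 0.0737) and Cry1 (0.15 ± 0.03, peak 17.1 h, adjusted p = 0.224) were not called over all genes.

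**Figure D1:**
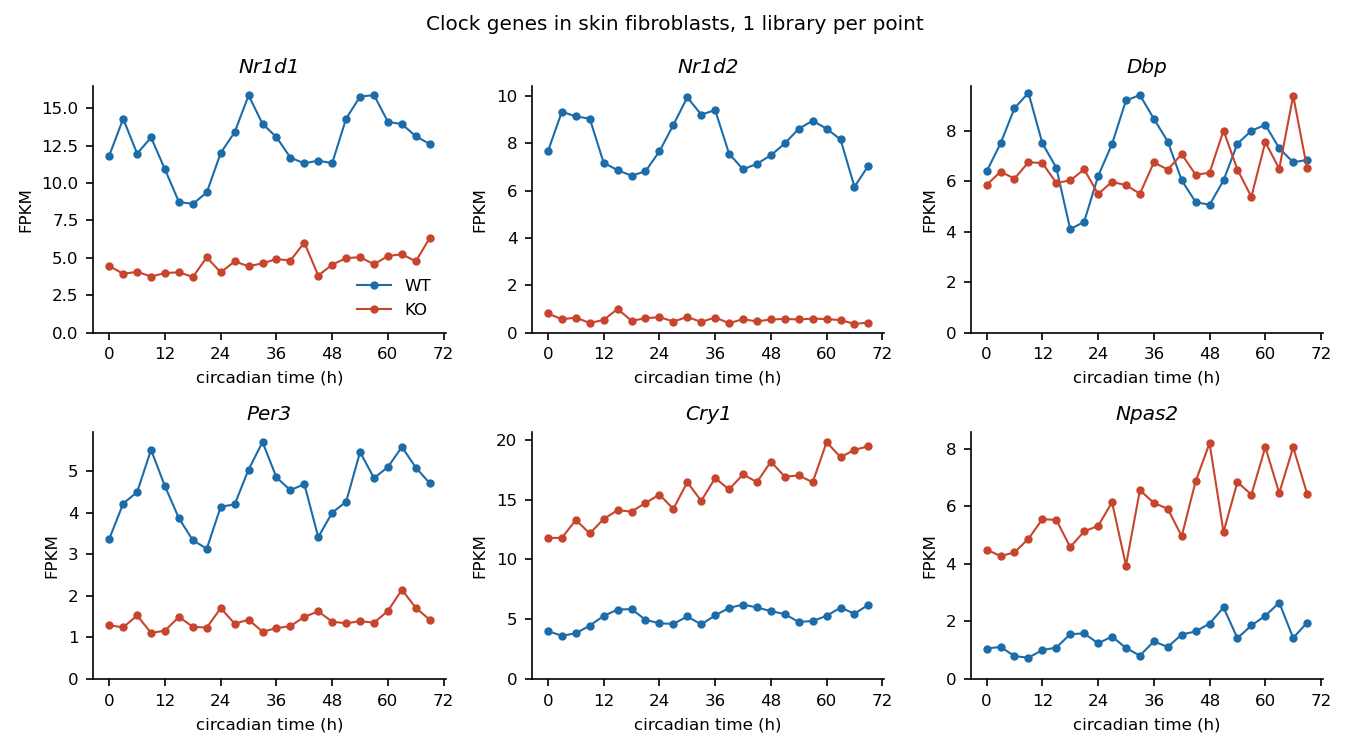
FPKM of clock genes against circadian time (h) in the MSF course, 1 value per time point for WT and KO, joined by lines. Nr1d1 swings between 8.6 and 15.87 FPKM in WT cells and lies between 3.719 and 6.325 FPKM in KO cells.

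In total 5 of 14658 genes were called in WT fibroblasts and 1060 had an unadjusted p below 0.05, where 733 would fall by chance. The count was 0 without the first or the second day and 3 without the third, 3 with no filter, 2 with no trend term, 41 with day as a factor and 8 on ranks. Leaving out 1 time point gave between 2 (CT21, CT33 or CT45) and 8 (CT15). It was 3 without any 1 of CT03, CT06, CT12, CT18, CT24, CT27, CT30, CT39, CT42, CT51 or CT66.

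In KO fibroblasts none of the 14713 genes tested was called by limma. The count at an unadjusted p below 0.05 was 873, against 736 by chance, and the lowest adjusted p was 0.11. With day as a factor 179 genes were called, prewhitened 2, and 1 without CT42. Arntl had an amplitude of 0.03 ± 0.03 (adjusted p = 0.969), Nr1d1 one of 0.02 ± 0.04 (adjusted p = 0.990) and Dbp one of 0.05 ± 0.04 (adjusted p = 0.957). The mean of the clock repressors and E-box outputs had an amplitude of 0.01 ± 0.02 (permutation p = 0.906). The difference of rhythms between the genotypes was called for 1 of 15065 genes, BC003965, whose waves peaked at 12.7 h in WT and 2.08 h in KO cells with amplitudes of 0.10 and 0.09 (adjusted p = 0.0128). The count of 1 went to 0 without CT03, CT15, CT27, CT36 or CT60, to 2 without CT45, CT51, CT66 or CT69 and to 4 without CT39. It was 0, 0 and 2 without day 1, 2 and 3, 2 with no trend term, 71 with day as a factor and 3 prewhitened. For the clock repressors and E-box outputs 0 of 15 differences were called over all genes (limma, 705 of all genes at an unadjusted p below 0.05, where 753 would fall by chance) and 7 when adjusted over the list alone. The largest of these was that of Dbp at 0.36 (adjusted p = 0.0697 over all genes), followed by Nr1d1 at 0.27 (0.135) and Per3 at 0.24 (0.156).

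The liver slices, pieces of tissue kept on membranes, posed the same question in a mixed tissue. In WT slices Arntl had an amplitude of 0.20 ± 0.06 with a peak at 18.6 h and was not called (adjusted p = 0.139, 24 time points). Vsig4, a complement receptor of Kupffer cells, had an amplitude of 1.21 ± 0.20 with a peak at 17.3 h, and Cd163, a scavenger receptor of macrophages, 1.14 ± 0.18 at 16.9 h. The complement genes C1qc (0.96 ± 0.18, peak 17.2 h) and C1qb (0.93 ± 0.17, peak 17.3 h) moved with them. Macrophage and Kupffer markers had 6 of 12 members called, 11 when adjusted over the list alone (Fisher's exact p adjusted to 1.23e-06), and their mean had an amplitude of 0.76 ± 0.15 with a peak at 17.3 h (permutation p adjusted to 0.0039). Endothelial markers had 4 of 11 called, 6 when adjusted over the list alone (adjusted p = 0.000574). The list mean of the endothelial markers had an amplitude of 0.38 ± 0.10, that of the ETS factors 0.20 ± 0.04 and that of the immediate early genes 0.07 ± 0.02 (permutation p adjusted to 0.0312, 0.0039 and 0.0191). Among them were Cdh5, the cadherin of endothelial junctions (0.74 ± 0.13, peak 17.5 h), Stab2, a scavenger receptor of sinusoids (0.68 ± 0.14), and Kdr, the receptor of VEGF (0.50 ± 0.10).

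ETS transcription factors had 4 of 17 members called in WT slices, 10 when adjusted over the list alone (adjusted p = 0.00251). They were Spi1, the factor of the myeloid lineage (0.69 ± 0.13, peak 17.7 h), Fli1 (0.42 ± 0.09), Ets1 (0.39 ± 0.08) and Elf1 (0.25 ± 0.05). Igfbp1, a secreted binding protein of insulin-like growth factors made by hepatocytes, peaked in the opposite part of the day at 6.01 h (amplitude 1.21 ± 0.27, adjusted p = 0.0480). Egr1, an immediate early gene (0.73 ± 0.15, peak 6.39 h), and Gdf15, a stress-induced cytokine (0.47 ± 0.10, peak 6.50 h), lay near it. No clock gene was called over all genes by limma, with 2852 of all genes at an unadjusted p below 0.05. Cry2 came closest (0.21, peak 6.38 h, adjusted p = 0.0865), Nr1d1 had an amplitude of 0.09 (adjusted p = 0.802), and 4 of the 5 clock activators that could be tested passed when adjusted over the list alone. Over all genes 289 of 14631 were called, where 732 of the 2852 would fall under an unadjusted p of 0.05 by chance, and 5 of the 289 had an amplitude of at least 1. Of the called genes 241 peaked late (median 17.8 h) and 48 early (median 6.22 h). The count moved with the settings, to 0 with no filter or on ranks, 0, 25 and 0 without day 1, 2 and 3, 796 with no trend term, 663 prewhitened and 1931 with day as a factor. No gene was called without any 1 of CT15, CT18, CT27, CT33, CT42, CT51, CT54, CT57 or CT66, while 70 were without CT09, 130 without CT03, 176 without CT00 and 185 without CT48. Leaving out CT24, CT39, CT63, CT36, CT30 or CT06 gave 460, 544, 577, 633, 646 and 1041 genes. Without CT66 and CT69, the WT libraries that correlated least with the others (median r of 0.863 and 0.862), 56 were called.

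**Figure D2:**
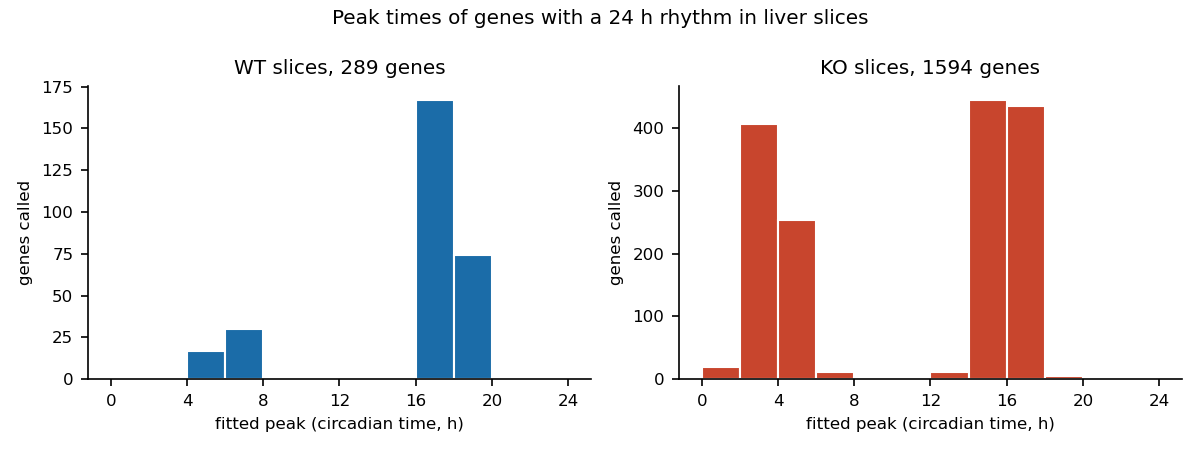
Number of genes called rhythmic against the fitted peak (h) in the liver slices, WT and KO. The WT peaks gather around 17.8 h (241 genes), and the KO peaks around 16 h (900 genes) and 3.74 h (694 genes).

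In KO slices Arntl had an amplitude of 0.16 ± 0.05 with a peak at 17.2 h and was not called (adjusted p = 0.0912). The 8 widest swings named by the rule were those of Col3a1, a chain of connective tissue collagen (1.88 ± 0.43, peak 4.69 h, adjusted p = 0.0266), Ly6d (1.70 ± 0.42, peak 5.73 h), Nbr1, an autophagy receptor (1.64 ± 0.37, peak 18.7 h), Spp1, which encodes osteopontin (1.38 ± 0.27, peak 4.48 h, adjusted p = 0.0153), Mmp7 (1.37), Col1a1 (1.32 ± 0.30), Ms4a8a (1.21) and Emilin1 (1.19). Lcn2, an acute phase protein, had one of 1.05 ± 0.20 (peak 3.82 h), and Timp1, an inhibitor of matrix proteases, one of 1.02 ± 0.24 (peak 3.95 h). A second set peaked near 16 h. It held Fosl1, an AP-1 subunit (0.61 ± 0.11, peak 15.8 h), Gclm of glutathione synthesis (0.44 ± 0.08, peak 16.4 h), the NAD-dependent deacetylase Sirt1 (0.41 ± 0.09, peak 16 h), and 4 clock genes. These were Nr1d1 (0.37 ± 0.08, peak 16.6 h, adjusted p = 0.0181), Per1 (0.28 ± 0.06, peak 16.4 h, adjusted p = 0.0253), Cry1 (0.26 ± 0.06, peak 16.4 h) and Clock (0.20 ± 0.05, peak 17.1 h, adjusted p = 0.0371).

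By list, fibroblast and matrix genes had 5 of 16 members called in KO slices (9 when adjusted over the list alone), macrophage and Kupffer markers 5 of 11, glucocorticoid response genes 5 of 16 (7 adjusted over the list alone) and clock repressors and E-box outputs 3 of 11 (4 adjusted over the list alone). The share of called genes passed against that of all genes in no list after adjustment (Fisher's exact adjusted p of 0.249, 0.127, 0.249 and 0.631 in the same order). The mean of the macrophage markers had an amplitude of 0.52 ± 0.15 with a peak at 3.32 h, that of the fibroblast genes 0.84 ± 0.26 at 4.70 h and that of the acute phase genes 0.39 ± 0.10 at 3.90 h (permutation p adjusted to 0.0329, 0.0329 and 0.0327). The fibroblast genes Postn (4.077 ± 9.755 FPKM) and Lox (10.5 ± 14.8) also had SDs above their means in KO slices. A few libraries may therefore carry part of the fibroblast wave. The mean of the immediate early genes peaked at 15.3 h (0.18 ± 0.05, adjusted p = 0.0327) and that of the clock repressors at 17 h (0.13 ± 0.04, adjusted p = 0.0329). Waves of the list mean also passed for the integrated stress response (0.16 ± 0.04, peak 16.4 h), proliferation (0.12 ± 0.03, peak 15.9 h), glucocorticoid response (0.14 ± 0.05, peak 4.42 h) and sex-linked genes (0.12 ± 0.03, peak 3.36 h). In total 1594 of 14224 genes were called in KO slices (4162 at an unadjusted p below 0.05, where 711 would fall by chance), 27 with an amplitude of at least 1. Of these, 900 peaked late (median 16 h) and 694 early (median 3.74 h). The count was 26 without CT09, CT27, CT39 and CT42, the 4 KO libraries that correlated least with the others (median r from 0.851 to 0.868), and 2734, 0 and 0 without day 1, 2 and 3. With no filter it was 702. Without CT15 alone 63 genes were called, and without CT42, CT27, CT54, CT30, CT63, CT48 or CT66 alone 624, 708, 796, 871, 890, 899 and 947.

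**Figure D3:**
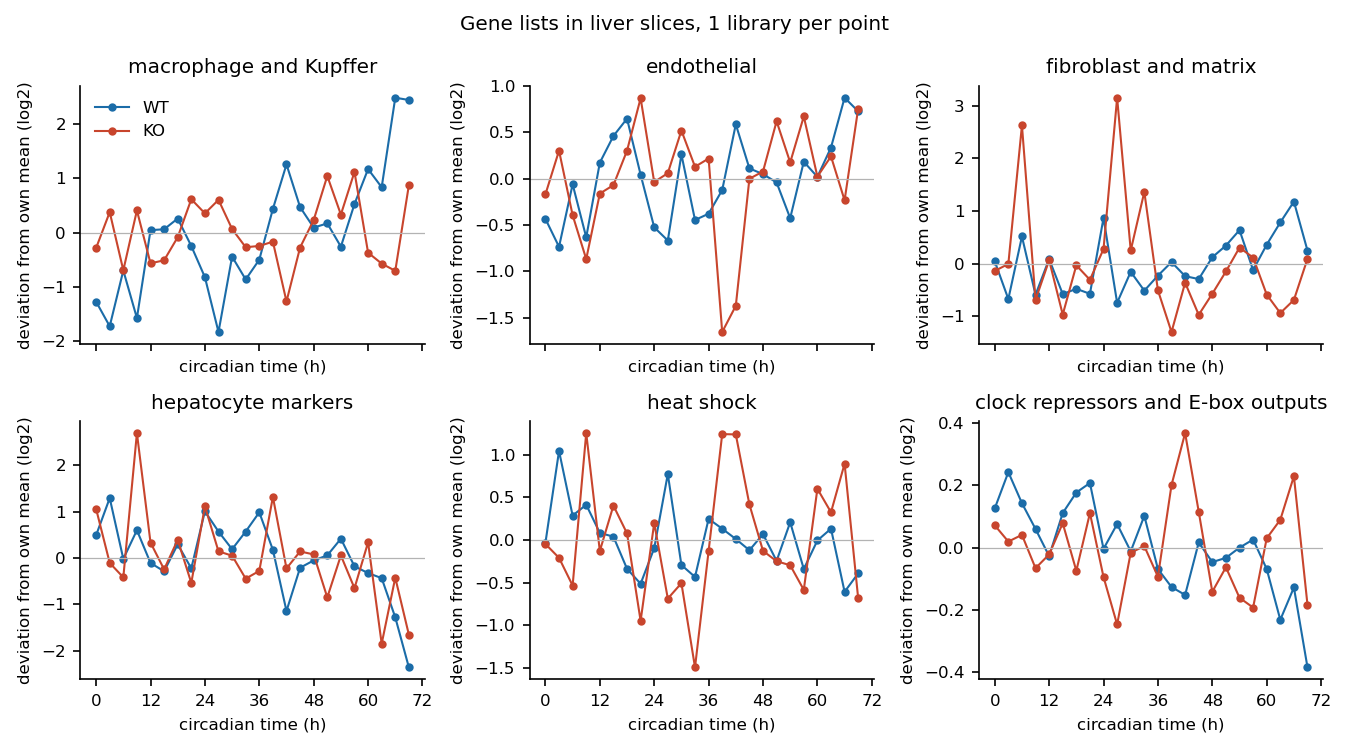
Mean log2(FPKM + 1) of gene lists in the liver slices against circadian time (h), as the deviation from the mean of each genotype. There is 1 value per time point for WT and KO, joined by lines, so levels cannot be compared between genotypes. By the 24 h fit the macrophage list peaks at 17.3 h in WT and at 3.32 h in KO slices.

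The rhythms themselves differed between WT and KO slices for 602 of 14566 genes (3334 at an unadjusted p below 0.05, where 728 would fall by chance). Arntl was not among them. Cry2 was the only one of 15 clock repressors and E-box outputs, with a difference of 0.31 (adjusted p = 0.0440). Macrophage and Kupffer markers had 7 of 12 members called, 10 when adjusted over the list alone (Fisher's exact p adjusted to 3.69e-06), led by C1qa (1.84, adjusted p = 0.00369), C1qc (1.70) and C1qb (1.62). Heat shock genes had 2 of 16 called (11 adjusted over the list alone), among them Hspb1, a small chaperone (1.22). Redox genes had 3 of 22 called (7 adjusted over the list alone), among them Nfe2l2, the NRF2 regulator of antioxidant genes (0.35). The WT and KO slices shared 20 called genes, where 31.4 would be shared by chance (Fisher's exact p = 0.992, one-sided), and 11 of the 20 peaked at least 8 h apart. No gene was called both in MSF and in slices of the same genotype. By chance 0.073 would be in WT and 0 in KO, where no MSF gene was called, so this shows nothing about shared rhythms. The 602 fell to 197 without WT CT66 and CT69, to 39 without the 4 KO libraries named above, to 1 and 0 without the second and the third day and to 173 with no filter. It rose to 1185 with no trend term, 1652 with day as a factor and 1026 prewhitened. Leaving out 1 time point gave between 71 (CT27) and 1112 (CT21), and 92, 106, 112, 163, 226, 232, 311, 328, 350, 380 and 398 without CT42, CT66, CT15, CT54, CT39, CT57, CT48, CT03, CT33, CT12 and CT00, and 962 without CT09.

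Between the genotypes, averaged over the 3 days, fibroblasts lacking Bmal1 had less Arntl mRNA. It measured 10.6 ± 0.75 FPKM in WT and 6.84 ± 0.56 in KO cells (SD, n = 24 each), a difference of -0.56 ± 0.03 on the log2 scale, lower at 24 of 24 time points and below the size limit of 1. A value per gene does not show whether a deleted exon is missing, so Arntl does not check the labels here. Other clock genes went in both directions. Nr1d2 differed by -2.52 ± 0.03 (8.01 to 0.563 FPKM), Hlf, a PAR bZIP factor, by -2.55 ± 0.14 and Nr1d1 by -1.27 ± 0.04, each lower at 24 of 24 time points. Cry1, a repressor of the clock, was higher by 1.44 ± 0.03 (5.17 to 15.8 FPKM) and Npas2, a paralog of Clock, by 1.48 ± 0.05, each at 24 of 24. Of 15 clock repressors and E-box outputs 6 were lower and 1 higher (camera adjusted p = 0.687, which compares the list with all genes).

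Genes of cell division were lower in KO fibroblasts. Of 24 proliferation genes 22 fell (camera adjusted p = 2.00e-09; adjusted p = 0.0641 with an estimated correlation), among them Ccna2, the cyclin of S phase (-3.18 ± 0.04), the proliferation marker Mki67 (-2.51 ± 0.03) and Top2a, a topoisomerase of dividing cells (-2.30 ± 0.04). Interferon response genes had 12 of 14 lower (adjusted p = 7.23e-06; adjusted p = 0.323 with an estimated correlation), with the chemokine Cxcl10 at -5.65 ± 0.08 and Irf7, a driver of type I interferon, at -2.25 ± 0.04. Cholesterol synthesis genes had 9 of 16 lower (adjusted p = 3.48e-06; adjusted p = 0.177 with an estimated correlation), including Sqle, an epoxidase of that pathway (-1.57 ± 0.02). Smooth muscle and stellate genes had 4 of 5 lower (adjusted p = 0.0063; adjusted p = 0.177 with an estimated correlation), with Cnn1, a calponin, at -2.68 ± 0.03. Heat shock genes had 2 of 16 lower (adjusted p = 0.0012; adjusted p = 0.155 with an estimated correlation). Ribosomal protein genes shifted up by camera with 1 of 14, Rps4x (1.04 ± 0.02), past the size limit (adjusted p = 0.0012; adjusted p = 0.177 with an estimated correlation).

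Among the largest single differences in fibroblasts, Art3 was at 252 ± 18.1 FPKM in WT cells and between 0 and 6.79 in KO cells (-7.37 ± 0.15), Igfbp5 at 287.5 ± 42 and 1.16 ± 0.71 (-7.12), Tnmd, a tendon protein, at 214 ± 36.6 and 0.566 ± 0.24 (-7.10) and Crabp1, which binds retinoic acid, at 504 ± 143 and 2.77 ± 0.86 (-7.05). In the other direction, Anxa8, an annexin, was at 0 to 0.106 FPKM in WT and 120 ± 23.8 in KO cells (6.83), Trf, transferrin, at 0 to 0.532 and 105 ± 8.20 (6.62), and Agt, angiotensinogen, at 2.49 ± 0.73 and 246.5 ± 44.2 (6.16). Thy1, a fibroblast surface marker, was lower by -2.49 ± 0.01, while Dcn, a matrix proteoglycan, was higher by 1.86 ± 0.02. In all 2416 of 15065 genes differed by at least 1 on the log2 scale, 936 higher and 1480 lower in KO cells, and 12235 passed by adjusted p alone. Genotype cannot be told apart from the culture, lanes and pools of its libraries, which it shares throughout the long courses.

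In the slices Arntl was at 4.50 ± 1.05 FPKM in WT and 4.09 ± 0.73 in KO tissue (SD, n = 24 each), a difference of -0.10 ± 0.05, lower at 16 of 24 time points, that turned to 0.22 when libraries were rescaled by median ratios. The authors' scale placed the median of all genes 0.34 lower in KO slices (-0.34 on the log2 scale), so rescaled differences of the genes named are given beside the deposited ones. Nr1d1 (-2 ± 0.08, rescaled -1.66), Nr1d2 (-1.68 ± 0.06, rescaled -1.36) and Dbp (-1.64 ± 0.10, rescaled -1.38) were lower at 24 of 24 time points. Cry1 (1.44 ± 0.05, rescaled 1.81) and Npas2 (1.26 ± 0.09, rescaled 1.49) were higher at 24 of 24. Of 6 clock activators 2 were higher (camera adjusted p = 0.000317; adjusted p = 0.0663 with an estimated correlation).

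Macrophage and Kupffer markers were lower in KO slices in 11 of 12 cases, 9 after rescaling (adjusted p = 0.00076; adjusted p = 0.628 with an estimated correlation), with C1qb at -2.59 ± 0.19 (rescaled -2.19) and Vsig4 at -2.41 ± 0.21 (rescaled -2.06). Heat shock genes shifted up with 3 of 16 past the size limit, 5 after rescaling (adjusted p = 2.30e-09; adjusted p = 0.37 with an estimated correlation). The inducible chaperones Hspa1b and Hspa1a, near-identical copies that share reads, differed by 2.80 ± 0.40 and 2.80 ± 0.39 (rescaled 3.19 and 3.17), and Hspa1b was at 28.5 ± 29.7 FPKM in WT and 241 ± 254 in KO slices, higher at 21 of 24 time points. Hepatocyte markers shifted up by camera (adjusted p = 3.48e-07; adjusted p = 0.624 with an estimated correlation) with 5 higher and 2 lower of 20, or 6 higher and none lower by limma after rescaling. Apoa2, an apolipoprotein (1.98 ± 0.25, rescaled 2.38), and Cyp2e1, a cytochrome P450 (1.75 ± 0.24, rescaled 2.13), were higher, while Hnf4a, the hepatocyte transcription factor, was lower on the deposited scale (-1.27 ± 0.19) and under the size limit after rescaling (-0.89). Bile acid and xenobiotic genes had 4 of 14 higher, 4 also after rescaling (adjusted p = 0.00193; adjusted p = 0.727 with an estimated correlation), including Cyp8b1 (1.47 ± 0.22, rescaled 1.74), which makes cholic acid. Cholesterol synthesis genes had 6 of 15 lower, but 1 of 15 after rescaling (adjusted p = 0.00454; adjusted p = 0.727 with an estimated correlation), with Sqle at -1.05 ± 0.09 and, rescaled, -0.67, below the size limit. The integrated stress response list shifted up with 1 of 12 past the size limit, or 2 after rescaling, among them Gdf15 (1.06 ± 0.12, rescaled 1.46) (adjusted p = 0.0105; adjusted p = 0.37 with an estimated correlation). Interferon and adipocyte lists had no member past the size limit by limma on the deposited scale, while Rsad2 (1.09, adjusted p = 1.82e-05) and Cfd (1.14, adjusted p = 0.0335) passed it after rescaling. Both lists shifted up relative to all genes (adjusted p = 0.0211 and 0.00454; adjusted p = 0.756 and 0.624 with an estimated correlation), although the medians of the interferon and integrated stress response lists were themselves below 0 (-0.17 and -0.07). In the adipocyte list Cfd was at 0.48 ± 0.43 FPKM in WT and 25.8 ± 94.5 in KO slices (SD, n = 24 each). Adipoq and Plin1 were at 5.80 ± 26.4 and 4.51 ± 21.3 FPKM in KO slices. Spreads this far above the means show that 1 or a few KO libraries carried them. Fibroblast and matrix genes had 8 of 16 lower, 7 after rescaling, without a shift of the list (camera adjusted p = 0.557).

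Among the 10 largest rises in KO slices were those of Elovl3, an elongase of fatty acids (1.47 ± 1.17 to 67.5 ± 88.5 FPKM, 4.35 ± 0.24, rescaled 4.65), Defb1, a defensin (3.08 ± 0.19, rescaled 3.38), Hamp2, a hepcidin (2.61, rescaled 2.97), and Bhmt, a methyltransferase of methionine metabolism (2.61, rescaled 2.93). Elovl3, Defb1 and Bhmt were each higher at 24 of 24 time points. The short RNA Mir1938 (3.12) was also among them, and was listed at 0 in 17 WT and 4 KO slices. Among the 10 largest falls were those of Trim12a, at 15.3 ± 3.67 FPKM in WT slices and listed at 0 in 21 of 24 KO slices (-3.98 ± 0.07, rescaled -3.79), Col3a1 (-3.14 ± 0.36, rescaled -2.80), Mup17, a major urinary protein with near-identical copies (rescaled -2.74), and Pf4 (-2.80 ± 0.24, rescaled -2.40), beside the short RNAs Mir130c (-3.23, rescaled -2.98) and Snord49a (-3.12, rescaled -2.91), which were listed at 0 in part of the libraries. The mitochondrial genes mt-Cytb and mt-Nd4 passed the test, but each was listed at 0 in 1 WT and 7 KO libraries and they were higher in KO slices at 11 and 13 and lower at 12 and 10 of 24 time points. No direction is therefore given for them. Their fitted differences went from -3.34 ± 1.31 and -3.10 ± 1.27 to -3.01 and -2.77 on rescaling, where the calls were lost (adjusted p of 0.0540 and 0.0683). In all 762 of 14566 genes differed, 172 higher and 590 lower in KO slices, and 305 higher and 212 lower after rescaling. By adjusted p alone 10603 passed, and a pseudocount of 0.1 gave 1397.

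**Figure D4:**
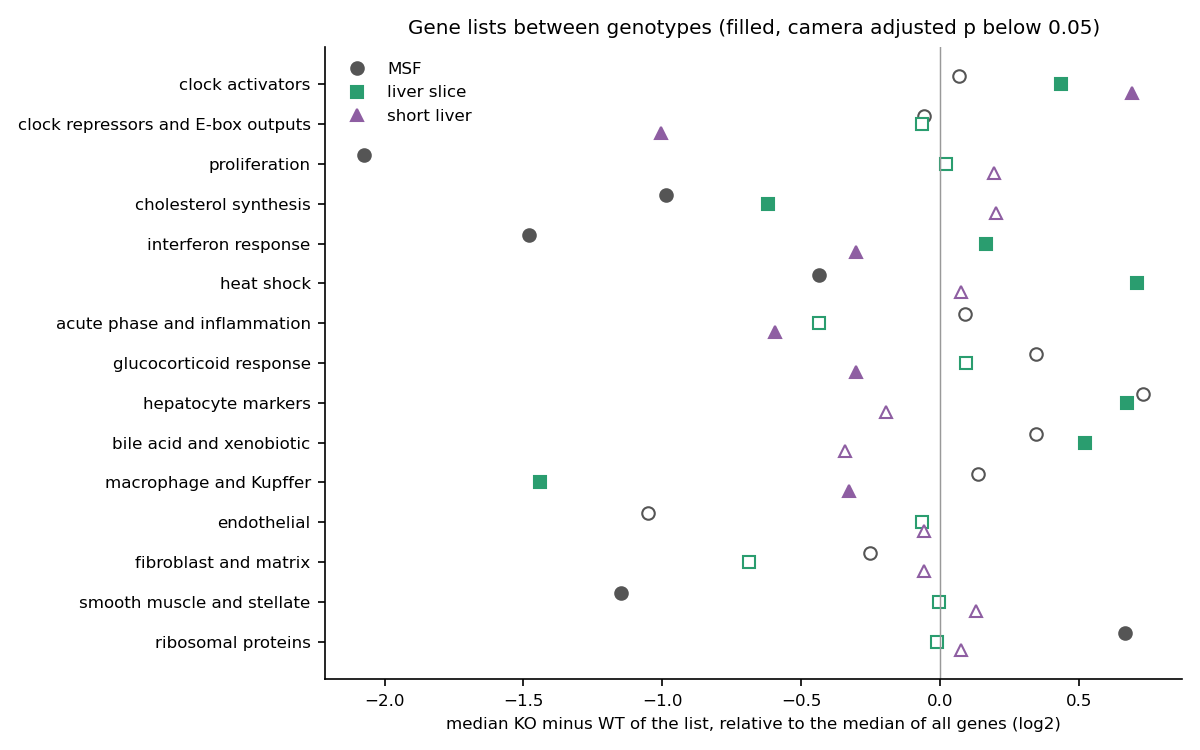
Median KO minus WT difference of each gene list relative to the median of all genes (log2) in the MSF, liver slice and short liver courses, filled where camera's adjusted p was below 0.05. Before that median was taken off, the list medians were -2.11 for proliferation in MSF, -1.78 for macrophage markers in the slices and -1.01 for clock repressors in the short course.

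The short liver course, with 3 replicates at each of 4 times, compared the genotypes without serial sampling over days. Samples of 1 genotype and number at different times may come from 1 animal, so the 12 samples of a genotype may stand for 3 sources. Calls are those of 12 samples against 12, and the fit of 3 means per genotype, 1 for each number, is given beside them. Arntl was higher in KO tissue, at 2.31 ± 0.51 against 1.45 ± 0.98 FPKM (SD, n = 12 each), a difference of 0.53 ± 0.08 (adjusted p = 0.000104, or 0.0389 with 3 means per genotype). Nr1d1 was at 37.3 ± 8.87 FPKM in WT and 1.16 ± 0.56 in KO, Dbp at 33.3 ± 24.8 and 1.01 ± 0.50 (-3.75 ± 0.05), Ciart, a repressor of the clock, at 37.5 ± 24.1 and 2.53 ± 1.99 (-3.33 ± 0.13), and Bhlhe41, the repressor DEC2, at 12.1 ± 8.26 and 0.208 ± 0.19 (-3 ± 0.14). Of 15 clock repressors and E-box outputs 10 fell and 2 rose, and of 5 clock activators 4 rose, led by Npas2 (2.39 ± 0.14). Both lists passed by camera with the preset correlation (adjusted p = 1.31e-10 and 3.94e-06) and with an estimated one (adjusted p = 0.0096 for each). With 3 means per genotype they passed by the preset correlation (4.55e-09 and 3.03e-05) but not by the estimated one (0.260 and 0.294).

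Acute phase and inflammation genes fell in 10 of 17 cases in the short course (adjusted p = 0.00078; adjusted p = 0.56 with an estimated correlation), including the serum amyloid Saa2 (-2.34 ± 0.50) and Socs3, an inhibitor of cytokine signalling (-1.33 ± 0.13). Macrophage markers had 5 of 13 lower, 7 when adjusted over the list alone (adjusted p = 0.00279; adjusted p = 0.753 with an estimated correlation), among them Marco (-1.29 ± 0.22) and C1qa (-0.58 ± 0.13). Interferon genes had 4 of 13 lower, 7 when adjusted over the list alone (adjusted p = 0.00752; adjusted p = 0.637 with an estimated correlation), and glucocorticoid response genes 7 lower and 2 higher of 16 (adjusted p = 0.01; adjusted p = 0.637 with an estimated correlation), including Per1 (-1.01 ± 0.07) and Klf9 (-0.49 ± 0.06). Outside the lists Lpl, lipoprotein lipase, was at 3.57 ± 1.32 FPKM in WT and 59.7 ± 25.1 in KO liver (3.63 ± 0.20), and Elovl3 again was higher (2.89). Serpina1e, an antitrypsin with near-identical copies, was lower by -4.51 ± 0.48, and Dio1, which activates thyroid hormone, by -3.28 ± 0.26. Single list members with large differences were Cidec, a lipid droplet protein (-2.13 ± 0.20), Alas1, the entry enzyme of heme synthesis (-1.65 ± 0.19), Pck1 of gluconeogenesis (-1.40 ± 0.17) and Nampt of NAD synthesis (-0.73 ± 0.09). In all 2350 of 12547 genes differed, 973 higher and 1377 lower, and 567 without replicate 3. With 3 means per genotype 560 were called, 193 higher and 367 lower, and 547 of them were among the 2350. The genes named here kept their calls, except Saa2, Marco and C1qa (adjusted p of 0.0662, 0.0503 and 0.122). Called members then went to 1 lower for acute phase, 0 for macrophage (by limma), 1 for interferon and 3 lower for glucocorticoid response genes, while these 4 lists still passed by camera (preset adjusted p of 0.000514, 0.00119, 0.00501 and 0.0165), none with an estimated correlation.

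**Figure D5:**
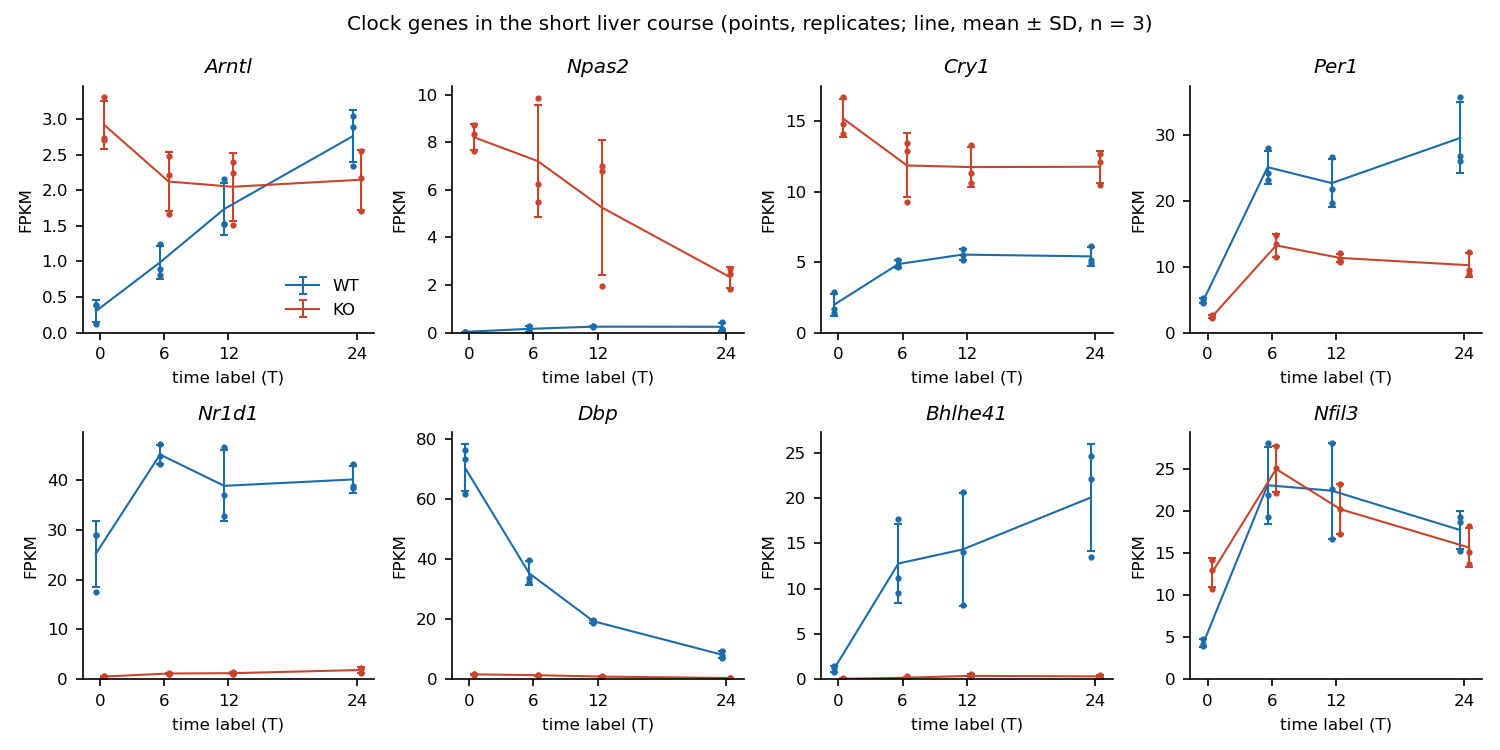
FPKM of 8 clock genes against the time label (T00 to T24) in the short liver course, with points for replicates and mean ± SD (n = 3) for WT and KO. Dbp falls from 70.4 to 8.15 FPKM in WT and stays below 1.7 in every KO sample.

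Over the 4 times Arntl rose from 0.301 ± 0.15 FPKM at T00 to 2.76 ± 0.37 at T24 in WT (1.53 ± 0.16, adjusted p = 1.51e-06; n = 3 per time) and was at 2.92 ± 0.34 and 2.15 ± 0.42 in KO, where it was not called (adjusted p = 0.13). Hepatocyte markers fell in 14 of 20 cases and rose in 1 in WT, and fell in 18 of 20 in KO. Pck1 at T24 was at -3.23 ± 0.35 in WT and -3.87 ± 0.35 in KO relative to T00, and Hnf4a at -2.31 ± 0.37 and -3.23 ± 0.37. Bile acid and xenobiotic genes fell in 10 and rose in 2 of 15 in WT and fell in 13 and rose in 1 of 15 in KO, with Cyp8b1 at -4.12 ± 0.41 in each. Acute phase and inflammation genes rose in 14 of 17 cases in each genotype, with the neutrophil chemokine Cxcl2 up by 7.16 ± 0.42 in WT and 7.09 ± 0.42 in KO and Ccl2, a monocyte chemokine, by 6.70 ± 0.39 and 6.77 ± 0.39. Integrated stress response genes rose in 12 of 12 (WT) and 10 of 12 (KO), including Gdf15 (5.81 ± 0.42 and 5.63 ± 0.42), and immediate early genes in 10 of 10 in each, including Fosl1 (5.28 ± 0.36 and 6.95 ± 0.36). Mt2, a metallothionein, rose from 14.9 ± 4.02 to 4210 ± 531 FPKM at T12 in WT and from 52.2 ± 32.6 to 2426 ± 250 in KO. Cholesterol synthesis genes fell in 6 and rose in 1 of 16 in WT and fell in 15 of 16 in KO.

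Among all genes 64.4% were called in WT and 72.2% in KO. Some of these lists had larger shares, but none passed against all genes (Fisher's exact adjusted p of at least 0.0801 in WT and 0.190 in KO). In WT 8081 of 12547 genes were called and in KO 9062. Without replicate 3 the WT count was 4420. Among clock genes Per1 rose in both genotypes (2.37 ± 0.14 at T24 in WT, 2.06 ± 0.14 at T06 in KO) and Dbp fell in both (-2.97 ± 0.11 and -0.92 ± 0.11 at T24). No mean or fold is given here for Alb, Serpina1b, Mup7 and mt-Nd2, each listed at 0 in some libraries: Alb was listed at 0 in 5 of 12 WT and 1 of 12 KO samples and lay at up to 25016 FPKM in the others.

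The time courses themselves differed between genotypes for 220 of 12547 genes (2291 at an unadjusted p below 0.05, where 627 would fall by chance). Arntl was among them, with a change over time that was 1.85 lower in KO than in WT (-1.85 on the log2 scale). Of 15 clock repressors and E-box outputs 6 were called, 8 when adjusted over the list alone (Fisher's exact p adjusted to 3.10e-06), and of 5 clock activators 2, or 4 when adjusted over the list alone (adjusted p = 0.0384). Dbp dropped from 70.4 ± 7.85 to 8.15 ± 1.18 FPKM in WT and from 1.57 ± 0.11 to 0.358 ± 0.07 in KO (n = 3 per time), and Bhlhe41 rose from 1.15 ± 0.33 to 20.1 ± 5.88 in WT, with KO values of 0.029 ± 0.04 and 0.296 ± 0.20. Redox genes had 3 of 22 called, 8 when adjusted over the list alone (adjusted p = 0.0555), including heme oxygenase, Hmox1, which went from 8.69 ± 0.83 to 570 ± 130 FPKM in WT and from 6.43 ± 0.68 to 1426 ± 120 in KO. Integrated stress response genes had 2 of 12 called, 6 when adjusted over the list alone (adjusted p = 0.117), including the hormone Fgf21, at 1.16 ± 0.31 and 7.21 ± 2.1 FPKM in WT and 0.18 ± 0.04 and 19.3 ± 6.82 in KO.

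The group means of several genes moved in opposite directions between T00 and T24. Sult1e1, the estrogen sulfotransferase, went from 0.0732 ± 0.03 to 38.8 ± 15.4 FPKM in WT and from 53.1 ± 58.6 to 11.7 ± 5.93 in KO. Glul, glutamine synthetase, went from 73.2 ± 4.17 to 206 ± 32.1 in WT and from 231 ± 19.9 to 81.3 ± 31.4 in KO, and its pseudogene Glns-ps1, which can share reads with it, followed. Id3, an inhibitor of bHLH factors, went from 16.2 ± 3.03 to 83.9 ± 8.46 in WT and from 51.1 ± 29.9 to 24.3 ± 4.88 in KO, where number 1 rose (19.96 to 28.52) and numbers 2 and 3 fell, and Sdr42e1 from 27.2 ± 4.79 to 97.5 ± 16.4 and from 48.5 ± 2.68 to 8.79 ± 3.21. The count of 220 fell to 62, 124 and 19 without replicate 1, 2 or 3, and was 368 with the replicate number as a block.

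Differences between the genotypes were shared across the courses in part. Of the genes tested in both slices and the short course, 56 were higher in KO in both, where 12.2 would be by chance, and 126 lower in both, where 55.4 would be (Fisher's exact p = 1.50e-23 and 9.61e-20, one-sided). After rescaling these counts were 76 and 44, and with 3 means per genotype in the short course 20 and 46, where 2.35 and 14.2 would be by chance. The differences had the same sign in 182 of 198 genes called in both (91.9%). Between MSF and slices 11 genes were higher in both (2.91 by chance, p = 0.000117, Fisher's exact) and 95 lower (30.9 by chance, p = 3.84e-24), or 22 and 29 after rescaling, and 106 of 154 had the same sign (68.8%). In all 3 courses 40 genes were called and 19 had 1 sign throughout. The 5 higher ones were Agt, Lpl, Npas2, Cry1 and the complement gene C3, and the 14 lower ones included Nr1d1, Nr1d2 and the water channel Aqp1. With 3 means per genotype 16 were called in all 3 courses and 12 had 1 sign throughout, without Agt, C3 and Aqp1. These counts over 3 courses use the deposited slice scale, on which KO slices lie lower. Lower genes near the size limit of 1 there, such as Aqp1 (-1.19), may lose their slice call on rescaling. Nr1d1 and Nr1d2 stayed past it (-1.66 and -1.36 rescaled).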

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

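The tests on slice libraries left out, on macrophage, fibroblast and hepatocyte lists, and on whole numbered sets below were chosen after the results were seen, while the regroupings, the 36 h fits, the heat shock covariate, the comparison lists and the random choices of libraries were set before. Results are given here when a test of the difference between genotypes passed.

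The daily waves differed between genotypes for 1 gene in MSF, BC003965 (adjusted p = 0.0128), and for 602 genes in the slices. Random exchange of genotype labels within time points gave at most 1 gene in MSF, reached by 2 of 100 exchanges including the real one. That count rests on 1 gene, was 0 without CT03, CT15, CT27, CT36 or CT60, and stood beside 705 genes at an unadjusted p below 0.05 where 753 would fall by chance, so chance stays open as its cause. In the slices the highest of the other exchanges gave 0 (1 of 100), which argues against a chance exchange of single libraries. Such exchanges treat the serial libraries of a genotype as separate, so they cannot exclude a few slices as the source. The slice count ran from 71 (without CT27) to 1112 (without CT21) over time points. The slice differences of named genes, which have no sign and include shifts of phase, were 1.84 for C1qa, 1.68 for Saa3, 1.61 for Postn, 1.22 for Hspb1, 1.17 for Cd38, 0.89 for Gdf15, 0.84 for Egr1, 0.81 for Kdr, 0.68 for Ptprc, 0.65 for Fli1, 0.49 for Por, 0.35 for Nfe2l2 and 0.31 for Cry2. In the short course 220 genes differed in their change over time, where the highest of the other regroupings of single samples gave 12 (1 of 100). Moving whole numbered sets of samples gave at most 3 in the other splits (1 of 10 reached 220), too few splits to exclude chance. Changes over time in KO minus those in WT were -1.85 for Arntl, -1.51 for Cry1, -2.94 for Bhlhe41, -1.53 for Nfil3, 2.04 for Dbp, 1.45 for Nr1d2 and 1.08 for Per3. Outside the clock they were -6.71 for Sult1e1, -4.81 for Gstm3, -4.20 for Sdr42e1, -3.60 for Crybb3, -3.41 for Glns-ps1, -3.18 for Id3, -3.07 for Ndrg1, -3.04 for Glul, 2.14 for Fgf21 and 1.73 for Hmox1. Rmrp (3.97) and Mir1938 (6.54) are short RNAs, and Mir1938 was listed at 0 in all T00 libraries and Rmrp in 1 KO library at T06, so these values carry little weight.

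The macrophage list rose and fell at nearly opposite times in WT and KO slices, with peaks 9.99 h apart. A difference of waves this large came with a permutation p of 0.0026, which decides nothing alone because the list was chosen for its phases. Adjusted over all 26 lists compared it was 0.0225. The permutation kept the WT wave fixed, so this argues only against a chance order of the KO slices. In all 4 of the 26 lists passed, which share the same slices and are not independent. Besides the macrophage list these were integrated stress response (peaks at 5.58 h in WT and 16.4 h in KO), clock repressors and E-box outputs (4.39 and 17 h) and immediate early genes (7.47 and 15.3 h). Each mean was over the genes tested in its own genotype. These were 12 in WT and 11 in KO for the macrophage list, 15 and 11 for clock repressors and 9 and 10 for immediate early genes. For these lists the waves compared are therefore partly of different genes. Within WT slices a lower share of hepatocytes would raise macrophage and fibroblast genes alike, but their waves differed (permutation p = 0.0007), which argues against it as the whole cause. The mean of the hepatocyte markers itself peaked at 6.49 h in WT slices (0.46 ± 0.17, permutation p adjusted to 0.122, not passed), opposite to the macrophage (17.3 h) and endothelial (17.4 h) lists, so a changing share may be part of the pattern. The macrophage markers had a median pairwise r of 0.821 in WT and 0.535 in KO slices, against 0.547 for hepatocyte markers in WT slices. A wave shared by the markers raises r whatever its source, so these values do not part a changing share of macrophage RNA from a daily change within cells, and both stay open.

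The 289 genes called in WT slices exceeded the highest of the other time orders, 2 (1 of 100), which argues against a chance order. A fit at 36 h called 1 gene by limma. It had 1539 genes at an unadjusted p below 0.05, where 732 would fall by chance, against 2852 at 24 h. This argues against a drift of that length as the whole source, but a contribution from slow drift stays open. Without CT66 and CT69 56 genes were called, but 50 of 100 choices of 2 libraries, the real one included, left as few (up to 1374), so libraries that stand apart cannot be told apart from the loss of other pairs.

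The 1594 genes called in KO slices exceeded the highest of the other time orders, 0 (1 of 100), and a fit at 36 h called 0 genes (limma, 1348 at an unadjusted p below 0.05). Without the 4 libraries that stood apart 26 were called, but 33 of 100 choices of 4 libraries, the real one included, left as few (up to 2520). With the mean heat shock level as a covariate 0 were called by limma, while the median amplitude of the genes went from 0.36 to 0.24 and the median SE from 0.08 to 0.07, and 29.6% of the other lists left as few. These were 8 of 27 (acute phase, clock repressors, fibroblast, immediate early, integrated stress response, interferon, macrophage and proliferation), while the other 19 left 3 to 3718 calls. A stress state that differs between slices therefore may contribute but cannot be told apart from what these 8 lists measure, and a biological rhythm without Bmal1 stays open beside it.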

How the results depend on the processing

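Leaving out each time point, chosen libraries or genes listed at 0, the fit to 1 mean per replicate number and the overlap alternatives were chosen after the results were seen. No value called in either setting changed sign (0), but 14 of 137 named slice differences did on rescaling, all below the size limit on both scales, such as Arntl (-0.10 to 0.22) and Nfil3 (-0.16 to 0.22), and slice calls went from 172 higher and 590 lower to 305 and 212. Named genes kept direction and side of the threshold in 13769 comparisons with an alternative, lost the call in 733 and gained it in 374, and list results in 61 and 19 (lost). The cause was not tested, except where fewer samples or genes, or the day factor, account for it by construction.

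MSF WT calls (5) were 3 with no filter, 2 with no trend term, 41 with day as a factor, 8 on ranks, and 0, 0 and 3 without day 1, 2 and 3. Single time points left out gave 2 (CT21, CT33, CT45) to 8 (CT15), and 3 without CT03, CT06, CT12, CT18, CT24, CT27, CT30, CT39, CT42, CT51 or CT66. MSF KO calls (0 by limma, 873 at an unadjusted p below 0.05) were 179 with day as a factor, 2 prewhitened, and 0 to 1 (CT42) over time points. Day as a factor leaves the drift within each day, which repeats every 24 h. Slice WT calls (289) were 0 with no filter, 796 with no trend term, 1931 with day as a factor, 663 prewhitened, 0 on ranks, 0, 25 and 0 without day 1, 2 and 3, 56 without CT66 and CT69, and 0 (CT15, CT18, CT27, CT33, CT42, CT51, CT54, CT57, CT66) to 1041 (CT06) over time points, with 70 without CT09, 130 CT03, 176 CT00, 185 CT48, 460 CT24, 544 CT39, 577 CT63, 633 CT36 and 646 CT30. Slice KO calls (1594) were 702 with no filter, 2734, 0 and 0 without day 1, 2 and 3, 26 without CT09, CT27, CT39 and CT42, and 63 (CT15) to 2209 (CT18) over time points, with 624 without CT42, 708 CT27, 796 CT54, 871 CT30, 890 CT63, 899 CT48 and 947 CT66.

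Differences of rhythms in MSF (1) were 2 with no trend term, 71 with day as a factor, 3 prewhitened, 0, 0 and 2 without day 1, 2 and 3, and 0 (CT03, CT15, CT27, CT36, CT60) to 4 (CT39) over time points, with 2 without CT45, CT51, CT66 or CT69. In slices (602) they were 173 with no filter, 1185 with no trend term, 1652 with day as a factor, 1026 prewhitened, 1 and 0 without day 2 and 3, 197 without WT CT66 and CT69, 39 without the 4 KO libraries, and 71 (CT27) to 1112 (CT21) over time points, with 92 without CT42, 106 CT66, 112 CT15, 163 CT54, 226 CT39, 232 CT57, 311 CT48, 328 CT03, 350 CT33, 380 CT12, 398 CT00 and 962 CT09.

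Genotype calls in MSF (2416) were 12235 with no size limit and 2402 to 2432 over time points. In slices (762) they were 10603 with no size limit, 1397 with a pseudocount of 0.1 and 714 to 831 over time points. In the short course they were 567 (without replicate 3) to 1793 against 2350, WT time calls 4420 (replicate 3) to 6880 against 8081, KO time calls 6392 to 8142 against 9062, and interaction calls 19 (replicate 3), 62 (replicate 1) and 124 (replicate 2) against 220, or 368 with a replicate block. With 1 mean per genotype and number, 3 against 3, the short genotype count was 560. The block changed no other count by over 1.5 times. The residual r of samples of 1 genotype and number at different times ran from -0.0809 to 0.216 (6 of 36 pairs over 0.1). Their mean r was above that of other numbers (permutation p = 0.0033), so a shared source per number may exist. The labels do not state it, so the planned fit was kept and that of 3 against 3 is given beside it. Of 21 list shifts 2 passed with an estimated correlation.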

Other observations

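The shared phase of MSF genes, the test of shared handling and the tests on replicate numbers were chosen after the results were seen, and the other tests before.

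Regrouping the samples gave the following for the remaining counts. The 5 genes called in WT fibroblasts exceeded the highest of the other time orders, 1 (1 of 100), which argues against a chance order of single libraries. The 36 h fit called 0 by limma (641 at an unadjusted p below 0.05). For the 0 genes called in KO fibroblasts the orders show nothing, since a count of 0 is reached by 100 of 100 whatever the data (the highest other gave 1), and the 36 h fit also called 0 (850 at an unadjusted p below 0.05). Genotype differences exceeded the highest other regrouping in MSF (2416 against 694) and slices (762 against 45), each reached by 1 of 100. This argues against a chance split of single libraries. The libraries of a genotype may share 1 culture or source, so a chance difference between sources cannot be excluded. The changes over time in the short course exceeded the highest other regrouping too (8081 against 5997 in WT, 9062 against 5776 in KO, 1 of 100 each). The high counts of other orders show that regroupings that partly follow time call many genes.

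In the short course the genotype count exceeded that of single samples exchanged within times (2350 against 234, 1 of 100). The labels join a number to the genotype at every time. Samples of 1 genotype and number deviated together (mean residual r of 0.0425 in WT and 0.0389 in KO, permutation p = 0.0033), as 1 animal per number would give. Mean r for other numbers was -0.0212 and -0.019. These values follow from the first 2, because the residuals of 3 replicates sum to 0 at each time. Exchanging single samples breaks such numbered sets. With 1 mean per set the count of 560 stood against at most 2 in the other splits (1 of 10), too few to exclude chance.

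In fibroblasts 15 genes had an unadjusted p below 0.01 in both genotypes, where 3.76 would by chance, and 11 of them peaked within 4 h of each other. The highest of the other time orders of the KO libraries gave 8 (1 of 100). Reordering the KO libraries alone also breaks noise shared by libraries of 1 time point, so this cannot exclude chance. The 11 included Junb, Ogt, Fubp1, Pnn, Hnrnpa2b1, Ccnl2, Rsrp1, Srsf5 and Spry2. Residuals of WT and KO libraries of 1 time point correlated more (mean r = 0.049) than those of different time points (-0.0021), with a permutation p of 0.0001, the smallest the permutations can give, consistent with handling shared by the harvests. A rhythm common to both genotypes may exist beside it and stays open.

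Genes within 20 Mb of Arntl on its chromosome were not called at a rate that differed past the threshold from other genes, in MSF (43 of 344, odds ratio 0.742, Fisher's exact p = 0.0743), slices (21 of 360, odds ratio 1.13, p = 0.55) or the short course (69 of 311, odds ratio 1.24, p = 0.122). Intervals of the odds ratios span 1, so DNA of the donor strain beside the gene stays open. Trim12a, 8.89 Mb away, was listed at 0 in 21 of 24 KO slices and 11 of 12 KO samples of the short course, and was at 30.9 ± 5.85 FPKM in WT and 16.1 ± 3.09 in KO fibroblasts (SD, n = 24 each).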
